A study of Homo sapiens with 24 samples.

How the data were processed

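Messenger RNA was measured in 24 libraries of NB4 and HL-60 cells, 3 per group in 8 groups: untreated, ATRA (1.0 µM), ATO (0.8 µM) and both drugs, with 48 h given in the labels of the treated libraries. The labels give no separate doses for the combination. The deposited table holds gene counts, which per the submitters' processing notes came from poly(A)-selected paired-end libraries trimmed with fastp, aligned to GRCh38 with HISAT2 and counted with featureCounts. The same notes name DESeq2 for the submitters' own tests. Tool versions, strandedness, the annotation release and whether reads or fragments were counted are not given in the sources used here. Even counts were over-represented among counts of 1 to 9 (74.4%, against 51.5% among counts of 500 or more), so the mates of a pair look to have been counted separately, and halved counts were tried as an alternative.

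The table held 60655 genes, of which 60400 (99.58%) were named and 58437 (96.34%) were found in GENCODE v29. The 44 pseudoautosomal Y copies held 0 counts. Library totals ran from 37811652 to 57795273 counts. The biological coefficient of variation was 8.78% in NB4, 7.0% in HL-60 and 7.98% in the fit of both lines, and sequencing depth adds counting error that is small beside it except for genes with few reads.

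Counts were analysed with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood tests after filterByExpr and TMM scaling, in a fit of the 12 libraries of each line (8 residual degrees of freedom), and of all 24 libraries for differences between the lines (16). The prior count was the edgeR default. There were 16 comparisons: 3 treatments against untreated, the combination against each drug and the interaction in each line, the 3 differences between lines, and the untreated lines. P-values were adjusted by the Benjamini-Hochberg method within a comparison and called below 0.05. In each of them 47 gene lists with 1069 members, all found in the table, were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, log2 CPM with a prior count of 2), and adjusted over the lists of a comparison.

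The text names genes by a rule fixed beforehand: the 6 largest called rises and falls of protein-coding genes for a treatment against untreated and 5 for other comparisons, with a mean of at least 5 CPM in the higher group and the same sign in each of 3 batches. It also covers a panel of 20 genes in both lines and, for each list, the 4 members with the smallest p and the uncalled member with the highest mean. Some genes named by this rule, 2 of the panel among them, are not reported here. Batch labels were checked as a pairing: residuals of libraries of the same batch correlated at -0.0812 to 0.0383 in NB4 and -0.00807 to 0.0589 in HL-60 (18 pairs each), so the batch was left out of the model.

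Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library sizes alone, every gene with at least 1 read, at least 1 CPM in 3 libraries, a replicate block, an adjusted p below 0.01, each library left out, only the groups compared, and all 24 libraries. Lists were also tested with an estimated correlation and with fry, and response correlations with a mean CPM of at least 10 and with a prior count of 2. The pipeline was tested on simulated data with 200 changed genes. In the NB4 ATRA simulation edgeR recovered 80.6% of 1.5-fold, 92.5% of 2-fold and 98.5% of 4-fold changes with 6.22% false calls, and for the interaction 65.7%, 79.1% and 98.5% with 4.71% false calls. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No sample was left out.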

Results

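The deposited counts covered 24 libraries from 2 leukaemia cell lines, NB4, an acute promyelocytic leukaemia (APL) line, and HL-60, a non-APL acute myeloid leukaemia line. Each line was left untreated or was grown for 48 h with all-trans retinoic acid (ATRA), which releases the block on myeloid differentiation, with arsenic trioxide (ATO), which degrades the PML-RARA fusion protein of APL, or with the pair of drugs. The series asked how differentiation treatment and the combination change transcription, with attention to DNA repair. Each group held 3 libraries, called batches in the labels. They are not said to be separate cultures, so the p-values measure only the spread between these samples. Culture time of untreated cells is not given and may differ in any comparison with them. Gene lists, the panel of named genes and the main settings were fixed before the data were examined, and the few alternatives added later are named as such.

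Unless stated otherwise, a number pair after a gene is its log2 change ± SE from edgeR (n = 3 libraries per group), a change was called at an adjusted p below 0.05, and levels are mean counts scaled to library size (CPM) ± SD over 3 libraries. Folds given as at least a value come from a group with 0 reads and a floor of 3 reads per library, and folds with a range carry a 95% counting interval. Those intervals and floors cover counting error only. Positions of the plotted genes are on GRCh38 with GENCODE v29: TGM2 on chromosome 20 from 38127387 to 38166578, ITGAM on chromosome 16 from 31259967 to 31332892, CD38 on chromosome 4 from 15778275 to 15853230, MPO on chromosome 17 from 58269856 to 58280935, HMOX1 on chromosome 22 from 35380361 to 35394214, MT2A on chromosome 16 from 56608199 to 56609497, MYC on chromosome 8 from 127735434 to 127741434 and PARP1 on chromosome 1 from 226360691 to 226408079.

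What ATRA alone did in NB4 was asked first. The transglutaminase gene TGM2 went from 0.0475±0.0494 to 5767±819 CPM, a rise of 121000-fold (41600 to 589000). The transcriptional repressor gene HIC1 rose at least 602-fold, the adhesion receptor gene CEACAM1 at least 578-fold, the lipase inhibitor gene ANGPTL4 at least 552-fold and the chemokine receptor gene CXCR5 at least 406-fold. In the other direction, the cytokine-like gene CYTL1 fell 1640-fold (281 to 62100) and THSD7A 90.5-fold (34.9 to 332), and STAB1 (-7.15±0.267), SOX18 (-6.88±0.387) and CHAT (-6.46±0.223) also fell. The integrin gene ITGAM, which encodes the myeloid surface marker CD11b, rose from 7.71±0.441 to 274±33.8 CPM, and CD38 (2.78±0.0596), CEBPE (2.16±0.0736), CDKN1A (3.98±0.238) and RARA (0.69±0.0921) rose with it.

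Among the other panel genes, PML (1.06±0.0658), HMOX1 (2.52±0.307) and ATM (0.35±0.0884) rose with ATRA in NB4 cells, and the retinoic acid hydroxylase gene CYP26A1 went from 0.0164±0.0285 to 2.32±0.626 CPM. Falls were called for MPO (-0.88±0.0723), MYC (-0.96±0.0682), GCLM (-0.63±0.0745) and MT2A (-2.58±0.0834) and for the repair and checkpoint genes CHEK1 (-0.62±0.0786) and PARP1 (-0.63±0.0573). BRCA1 passed at -0.26 with 2 of 3 batches falling, and lost the call without NB4 ATRA replicate 3 (-0.18, adjusted p = 0.124).

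Genes of mature myeloid surface receptors rose together, and 29 of 31 measured members rose, 1 fell and 1 did not pass (the same adjusted over the list alone), a median log2 change of 3.39. Camera called mature myeloid surface receptors higher (adjusted p = 1.21e-12, and adjusted p = 0.0622 with an estimated correlation). Their clearest members were ITGAM (5.15±0.0915), ICAM3 (3.71±0.0808) and PTAFR (4.39±0.0964). For interferon-stimulated genes, 33 of 37 measured members rose, 1 fell and 3 did not pass (the same adjusted over the list alone), a median log2 change of 2.28 (2.08 at the floor), led by OAS3 (4.81±0.11), DTX3L (2.09±0.0731) and IFI6 (4.12±0.149). Camera called interferon-stimulated genes higher (adjusted p = 7.65e-10, and adjusted p = 0.0517 with an estimated correlation). In NADPH oxidase, the enzyme of the respiratory burst, 9 of 10 measured members rose and 1 fell (the same adjusted over the list alone), a median log2 change of 1.98, with PRAM1 (5.48±0.0831), NCF1 (9.95±0.174) and CYBB (3.31±0.0713). Camera called NADPH oxidase higher (adjusted p = 7.1e-06, and adjusted p = 0.0622 with an estimated correlation).

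In ribosome biogenesis, 31 of 32 measured members fell and 1 did not pass (the same adjusted over the list alone), a median log2 change of -0.82, with POLR1B (-1.29±0.0714), UTP20 (-1.45±0.0883) and NPM1 (-1.05±0.0673). Camera called ribosome biogenesis lower (adjusted p = 8.83e-12, and adjusted p = 0.0898 with an estimated correlation). In mismatch repair, 13 of 15 measured members fell and 2 did not pass (the same adjusted over the list alone), a median log2 change of -0.44, with RFC3 (-0.87±0.0655) and EXO1 (-1.11±0.0846). Camera called mismatch repair lower (adjusted p = 0.000246, and adjusted p = 0.217 with an estimated correlation). In DNA replication, 3 of 35 measured members rose, 24 fell and 8 did not pass (the same adjusted over the list alone), a median log2 change of -0.28, with MCM6 (-0.73±0.0634) and CDC6 (-0.75±0.0659) lower and RRM2 (0.75±0.0558) higher. Camera called DNA replication lower (adjusted p = 0.000356, and adjusted p = 0.186 with an estimated correlation). The primary granule proteins split, and 5 of 14 measured members rose, 8 fell and 1 did not pass (the same adjusted over the list alone), a median log2 change of -1.02 but a mean of 0.60, with DEFA4 (7.06±0.0904) and BPI (10.7±0.183) up and CTSG (-3.53±0.107) down. Camera did not call primary granule proteins (adjusted p = 0.231). Among p53 target genes, 14 of 27 measured members rose, 4 fell and 9 did not pass (14 rose and 5 fell adjusted over the list alone), a median log2 change of 0.49, and BTG2 (5.57±0.2) and GADD45A (2.71±0.128) were the clearest rises. Camera did not call p53 target genes (adjusted p = 0.0709). In edgeR, 9806 of 16370 genes passed (5117 higher and 4689 lower), 3729 of them by at least 2-fold and 9638 with the same sign in all 3 batches. Camera called 15 of 47 lists higher and 7 lower, and none of these calls held with an estimated correlation. Replicate 2 with ATRA stood apart, with a chi-square per degree of freedom of 44.6 and 23.0 in its pairs against 17.2 in the remaining pair. Between 9197 and 9790 genes were called without 1 library.

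ATO alone was asked the same question in NB4. The haem oxygenase gene HMOX1, a target of the oxidative stress factor NRF2, rose from 0.293±0.191 to 15.1±1.46 CPM (5.64±0.242, adjusted p = 1.05e-13). The oxidase subunit gene NCF1, the kinase gene FGR and the adaptor gene PRAM1 rose too (5.24±0.164, 5.03±0.174 and 3.95±0.0786), as did CD52 (3.78±0.161) and ALOX5AP (3.78±0.138). Large falls were in CYTL1 (-5.84±0.243), CYP1B1 (-3.36±0.136), CHAT (-3.27±0.169) and PTPN3 (-2.99±0.132).

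Panel genes that rose with ATO in NB4 cells were ITGAM (1.58±0.0875), CEBPE (1.00±0.0718), PML (0.44±0.0655), GCLM (0.60±0.0729) and MT2A (1.32±0.0764), and those that fell were MYC (-0.82±0.0679), MPO (-0.33±0.0718), CHEK1 (-0.35±0.078) and PARP1 (-0.27±0.057). TGM2 stayed at 0.0557±0.0225 CPM and did not pass (adjusted p = 0.856), nor did CD38 (-0.10±0.0568, adjusted p = 0.163) and BRCA1 (-0.21±0.0984, adjusted p = 0.10).

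For NRF2 target genes, 19 of 27 measured members rose, 3 fell and 5 did not pass (the same adjusted over the list alone), a median log2 change of 0.59, with SLC48A1 (2.03±0.0678), FTL (0.90±0.0614) and TKT (0.92±0.0644). Camera called NRF2 target genes higher (adjusted p = 8.41e-06, and adjusted p = 0.215 with an estimated correlation). For metallothioneins, which bind arsenic and other metals, 3 of 4 measured members rose and 1 did not pass (4 rose adjusted over the list alone), a median log2 change of 1.38, with MT1X (2.00±0.14) and MT1F (1.44±0.182). Camera called metallothioneins higher (adjusted p = 0.00461, and adjusted p = 0.132 with an estimated correlation). For mitochondrially encoded mRNAs, 13 of 13 measured members fell (the same adjusted over the list alone), a median log2 change of -0.76. All genes of the mitochondrial genome together held 4.83±0.601% of counts in untreated and 3.43±0.45% in ATO libraries. Camera called mitochondrially encoded mRNAs lower (adjusted p = 9.66e-06, and adjusted p = 0.466 with an estimated correlation). In the unfolded protein response, 2 of 19 measured members rose, 14 fell and 3 did not pass (2 rose and 16 fell adjusted over the list alone), a median log2 change of -0.52, with HSPA5 (-0.97±0.0589), HSP90B1 (-1.05±0.0787) and CALR (-0.71±0.0575). Camera called the unfolded protein response lower (adjusted p = 2.98e-06, and adjusted p = 0.132 with an estimated correlation).

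In ribosome biogenesis under ATO, 27 of 32 measured members fell and 5 did not pass (29 fell adjusted over the list alone), a median log2 change of -0.40, with NPM1 (-0.75±0.0669), NCL (-0.68±0.0623) and NOP14 (-0.67±0.062). By camera ribosome biogenesis moved lower (adjusted p = 3.14e-10, and adjusted p = 0.132 with an estimated correlation). For homologous recombination, 3 of 30 measured members rose, 12 fell and 15 did not pass (4 rose and 13 fell adjusted over the list alone), a median log2 change of -0.21, with XRCC2 (-0.59±0.0818), RBBP8 (-0.58±0.0959) and NBN (-0.57±0.0951). Camera called homologous recombination lower (adjusted p = 0.0207, and adjusted p = 0.487 with an estimated correlation). For mismatch repair, 1 of 15 measured members rose, 8 fell and 6 did not pass (the same adjusted over the list alone), a median log2 change of -0.22. By camera mismatch repair moved lower (adjusted p = 0.0383, and adjusted p = 0.488 with an estimated correlation). In edgeR, 6674 of 16370 genes passed (3466 higher and 3208 lower), 1471 of them by at least 2-fold and 6584 with the same sign in all 3 batches. Camera called 8 of 47 lists higher and 8 lower, and none of these calls held with an estimated correlation. With library sizes alone the log2 changes of all genes moved by a median of 0.107 and the share of called genes that were higher went from 51.9% to 69%, so the balance of rises and falls depends on scaling. Between 5651 and 6116 genes were called without 1 library.

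The combination in NB4 cells carried the question of repair repression. TGM2 reached 11880±654 CPM, a rise of 250000-fold (85500 to 1210000), and HIC1 rose at least 920-fold, the platelet selectin gene SELP at least 509-fold, AQP9 at least 387-fold and the prostaglandin synthase gene PTGES 10000-fold (2920 to 87100). CYTL1 fell 1770-fold (339 to 74700), the endothelial factor gene SOX18 812-fold (155 to 34300) and the matrix gene EMILIN2 286-fold (118 to 849), with CHAT (-5.74±0.205), STAB1 (-5.74±0.224) and TERT (-6.76±0.233), the last encoding the catalytic part of telomerase. Among panel genes, ITGAM (5.50±0.0925), CDKN1A (4.01±0.237), CD38 (2.91±0.0599) and CEBPE (2.44±0.0742) rose, while the proto-oncogene MYC fell from 567±33.5 to 113±9.99 CPM and the granule enzyme gene MPO from 9395±361 to 2090±300 CPM (-2.33±0.0711 and -2.17±0.0749). Rises were also called for HMOX1 (6.58±0.237), MT2A (1.65±0.077), PML (1.12±0.0657), RARA (0.97±0.0917) and ATM (0.62±0.0884).

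The repair and damage checkpoint genes were mostly lower after the combination. PARP1, which senses strand breaks, went from 604±16 to 303±21.3 CPM (-0.99±0.0576, adjusted p = 8.16e-13), and the checkpoint kinase gene CHEK1 from 121±5.71 to 66.6±2.76 CPM (-0.87±0.0788, adjusted p = 1.83e-09). BRCA1 (-0.18±0.0984, adjusted p = 0.108) and GCLM (0.11±0.0731, adjusted p = 0.209) did not pass. The 8 repair and checkpoint lists, not all described, were pooled after the data were seen. Of 163 members, 101 fell (62%, all tested genes 32.8%) and 34 rose, a median of -0.37. With ATRA alone 88 fell (54%, all genes 28.6%) and 30 rose, and with ATO alone 63 (38.7%, 19.6%) and 22. The interaction median was -0.0004. The 9-list DNA damage response class fixed beforehand gave 108 falls and 49 rises of 187, a median of -0.33.

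By pathway in NB4 cells given the combination, for homologous recombination, 7 of 30 measured members rose, 20 fell and 3 did not pass (the same adjusted over the list alone), a median log2 change of -0.35, with XRCC2 (-1.64±0.0846), EXO1 (-1.25±0.0846), RAD54L (-1.02±0.0798) and PALB2 (-1.14±0.0923). By camera homologous recombination moved lower (adjusted p = 0.0148, and adjusted p = 0.38 with an estimated correlation). For non-homologous end joining, 4 of 18 measured members rose, 12 fell and 2 did not pass (5 rose and 12 fell adjusted over the list alone), a median log2 change of -0.65, with SHLD2 (-2.12±0.0897), PRKDC (-0.98±0.0618) and XRCC6 (-0.72±0.0532). Camera called non-homologous end joining lower (adjusted p = 0.03, and adjusted p = 0.286 with an estimated correlation). For mismatch repair, 13 of 15 measured members fell and 2 did not pass (the same adjusted over the list alone), a median log2 change of -0.64, with MSH6 (-1.15±0.0755) and PMS1 (-1.47±0.1). Camera called mismatch repair lower (adjusted p = 0.000317, and adjusted p = 0.257 with an estimated correlation). For base excision repair, 7 of 24 measured members rose, 14 fell and 3 did not pass (the same adjusted over the list alone), a median log2 change of -0.32, with UNG (-1.87±0.0675) and APEX1 (-1.19±0.0671). By camera base excision repair did not pass (adjusted p = 0.0688). For the Fanconi anaemia pathway, 3 of 20 measured members rose, 12 fell and 5 did not pass (the same adjusted over the list alone), a median log2 change of -0.38, with USP1 (-1.10±0.0834) and FANCE (-1.02±0.119). Camera called the Fanconi anaemia pathway lower (adjusted p = 0.0425, and adjusted p = 0.24 with an estimated correlation).

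For damage checkpoint signalling after the NB4 combination, 6 of 26 measured members rose, 16 fell and 4 did not pass (the same adjusted over the list alone), a median log2 change of -0.35, with CDC25A (-1.31±0.0649). Camera called damage checkpoint signalling lower (adjusted p = 0.0225, and adjusted p = 0.286 with an estimated correlation). For nucleotide excision repair, 5 of 22 measured members rose, 11 fell and 6 did not pass (the same adjusted over the list alone), a median log2 change of -0.22. Camera did not call nucleotide excision repair (adjusted p = 0.151). In DNA replication, 3 of 35 measured members rose, 27 fell and 5 did not pass (the same adjusted over the list alone), a median log2 change of -0.56, with MCM7 (-1.86±0.0652) and MCM4 (-1.28±0.0592). By camera DNA replication moved lower (adjusted p = 1.46e-05, and adjusted p = 0.12 with an estimated correlation). Among p53 target genes, 16 of 27 measured members rose, 8 fell and 3 did not pass (the same adjusted over the list alone), a median log2 change of 0.79, with BTG2 (3.98±0.202) up and AEN (-1.67±0.0706) and TRIAP1 (-1.45±0.081) down. Camera did not call p53 target genes (adjusted p = 0.156).

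Of ribosome biogenesis, 32 of 32 measured members fell (the same adjusted over the list alone), a median log2 change of -1.47. Camera called ribosome biogenesis lower (adjusted p = 1.61e-13, and adjusted p = 0.0982 with an estimated correlation). For the unfolded protein response, 3 of 19 measured members rose, 14 fell and 2 did not pass (the same adjusted over the list alone), a median log2 change of -0.86. By camera the unfolded protein response moved lower (adjusted p = 0.000403, and adjusted p = 0.0982 with an estimated correlation). In edgeR, 11164 of 16370 genes passed (5795 higher and 5369 lower), 5316 of them by at least 2-fold and 11042 with the same sign in all 3 batches. Camera called 18 of 47 lists higher and 12 lower, and none of these calls held with an estimated correlation. Between 10757 and 10811 genes were called without 1 library.

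**Figure D1:**
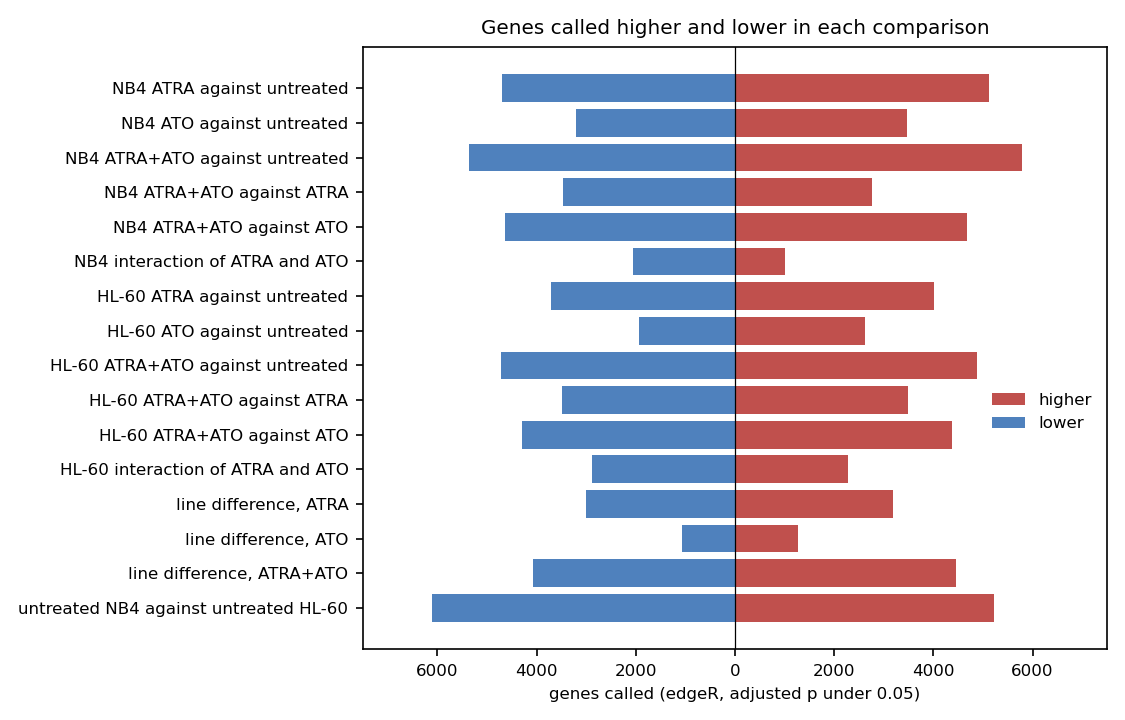
Numbers of genes called higher (red) and lower (blue) in each of the 16 comparisons in edgeR at an adjusted p below 0.05, n = 3 libraries per group.

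What ATO added to ATRA in NB4 was asked directly. The metallothionein gene MT2A rose from 20.0±2.77 to 377±24.5 CPM and HMOX1 from 1.74±0.543 to 28.9±0.524 CPM (4.23±0.0878 and 4.05±0.186). MT1X (3.18±0.151), SLC4A3 (3.14±0.382), GCLM (0.74±0.0743) and TGM2 (1.04±0.0817) were higher as well. The interferon-induced chemokine gene CXCL10 and the cytokine gene LIF fell (-4.25±0.33 and -2.74±0.241), with STC1 (-3.40±0.306) and FLT1 (-3.05±0.203), and MYC (-1.37±0.0693), MPO (-1.29±0.0729) and PARP1 (-0.36±0.0573) fell further.

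By list, for metallothioneins, 4 of 4 measured members rose (the same adjusted over the list alone), a median log2 change of 3.13. By camera metallothioneins moved higher (adjusted p = 3.96e-06, and adjusted p = 0.0552 with an estimated correlation). For NRF2 target genes, 15 of 27 measured members rose, 2 fell and 10 did not pass (17 rose and 4 fell adjusted over the list alone), a median log2 change of 0.30. By camera NRF2 target genes moved higher (adjusted p = 3.96e-05, and adjusted p = 0.305 with an estimated correlation). For ribosome biogenesis, 31 of 32 measured members fell and 1 did not pass (the same adjusted over the list alone), a median log2 change of -0.62. By camera ribosome biogenesis moved lower (adjusted p = 2.69e-15, and adjusted p = 0.103 with an estimated correlation). For mitochondrially encoded mRNAs, 13 of 13 measured members fell (the same adjusted over the list alone), a median log2 change of -0.88. By camera mitochondrially encoded mRNAs moved lower (adjusted p = 2.17e-06, and adjusted p = 0.391 with an estimated correlation). For cytosolic ribosomal proteins, 18 of 47 measured members fell and 29 did not pass (the same adjusted over the list alone), a median log2 change of -0.13, which turned to 0.0188 with library sizes alone. Camera called cytosolic ribosomal proteins lower (adjusted p = 0.00485, and adjusted p = 0.526 with an estimated correlation). In edgeR, 6219 of 16370 genes passed (2754 higher and 3465 lower), 1245 of them by at least 2-fold and 5902 with the same sign in all 3 batches. Camera called 8 of 47 lists higher and 14 lower, and none of these calls held with an estimated correlation. With library sizes alone all log2 changes moved by a median of 0.144 and the share of called genes that were higher went from 44.3% to 68.4%. Between 5248 and 6113 genes were called without 1 library.

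What ATRA added to ATO in NB4 was asked next. TGM2 rose 213000-fold (82800 to 778000), PTGES 12200-fold (3310 to 98600), the retinoic acid hydroxylase gene CYP26B1 at least 1140-fold, the macrophage gene MPEG1 at least 436-fold and DAAM2 at least 315-fold. EMILIN2 fell 115-fold (46.9 to 340), with STAB1 (-5.10±0.225), PRRT4 (-4.95±0.169) and CST7 (-4.33±0.132). Panel genes that rose were ITGAM (3.92±0.0832), CD38 (3.01±0.0601), CDKN1A (4.55±0.246) and ATM (0.81±0.0886), and MPO (-1.84±0.0741), MYC (-1.50±0.0695), PARP1 (-0.72±0.0574) and CHEK1 (-0.52±0.0786) fell.

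For interferon-stimulated genes, 34 of 37 measured members rose, 1 fell and 2 did not pass (the same adjusted over the list alone), a median log2 change of 1.6. By camera interferon-stimulated genes moved higher (adjusted p = 1.55e-10, kept at adjusted p = 0.0415 with an estimated correlation). For retinoid response genes, 19 of 22 measured members rose, 1 fell and 2 did not pass (20 rose and 1 fell adjusted over the list alone), a median log2 change of 2.91 (2.68 at the floor). Camera called retinoid response genes higher (adjusted p = 1.8e-09, and adjusted p = 0.096 with an estimated correlation). In DNA replication, 2 of 35 measured members rose, 25 fell and 8 did not pass (2 rose and 26 fell adjusted over the list alone), a median log2 change of -0.40. Camera called DNA replication lower (adjusted p = 5.12e-06, and adjusted p = 0.12 with an estimated correlation). In edgeR, 9312 of 16370 genes passed (4676 higher and 4636 lower), 3266 of them by at least 2-fold and 9240 with the same sign in all 3 batches. Camera called 16 of 47 lists higher and 12 lower, and 1 of these calls held with an estimated correlation. Between 8574 and 8794 genes were called without 1 library.

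The interaction in NB4 asked where the combination departed from the sum of the separate log2 changes. MT2A lay 2.92±0.111 above it: ATRA alone lowered MT2A and the combination raised it. HMOX1 lay below the sum (-1.59±0.353), as did ITGAM (-1.23±0.114), MPO (-0.96±0.102), MYC (-0.55±0.096) and CEBPE (-0.73±0.0998). AQP9 was below the sum, at 0 CPM untreated, 0.492±0.0814 with ATO, 26±2.18 with ATRA and 27.8±8.99 with both. CYP26B1 was above it, at 0 CPM with ATO, 69.6±15.3 with ATRA and 71.9±12.3 with both, but not in limma-voom (4.02, adjusted p = 0.12). Each had a group without reads, so the prior count set the size of its departure.

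Among the lists in the NB4 interaction, for MHC class I presentation, 13 of 15 measured members lay below the sum and 2 did not pass (the same adjusted over the list alone), a median log2 change of -0.94, with PSME1 (-1.04±0.0829), HLA-E (-1.40±0.126) and B2M (-0.84±0.0802). Camera called MHC class I presentation lower (adjusted p = 1.69e-09, and adjusted p = 0.0949 with an estimated correlation). For NADPH oxidase, 8 of 10 measured members lay below the sum and 2 did not pass (1 lay above the sum and 8 lay below the sum adjusted over the list alone), a median log2 change of -0.57, with PRAM1 (-3.64±0.101) and NCF1 (-4.63±0.2). By camera NADPH oxidase moved lower (adjusted p = 6.48e-06, and adjusted p = 0.0949 with an estimated correlation). For primary granule proteins, 2 of 14 measured members lay above the sum, 10 lay below the sum and 2 did not pass (the same adjusted over the list alone), a median log2 change of -0.99, with DEFA4 (-4.04±0.105) and BPI (-4.42±0.278). Camera called primary granule proteins lower (adjusted p = 6.48e-06, and adjusted p = 0.204 with an estimated correlation). In edgeR, 3056 of 16370 genes passed (1005 above the sum and 2051 below it), 815 of them by at least 2-fold and 2965 with the same sign in all 3 batches. Camera called 1 of 47 lists higher and 12 lower, and none of these calls held with an estimated correlation. Between 2399 and 4305 genes were called without 1 library, with 4305 when NB4 ATRA replicate 2 was left out.

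**Figure D2:**
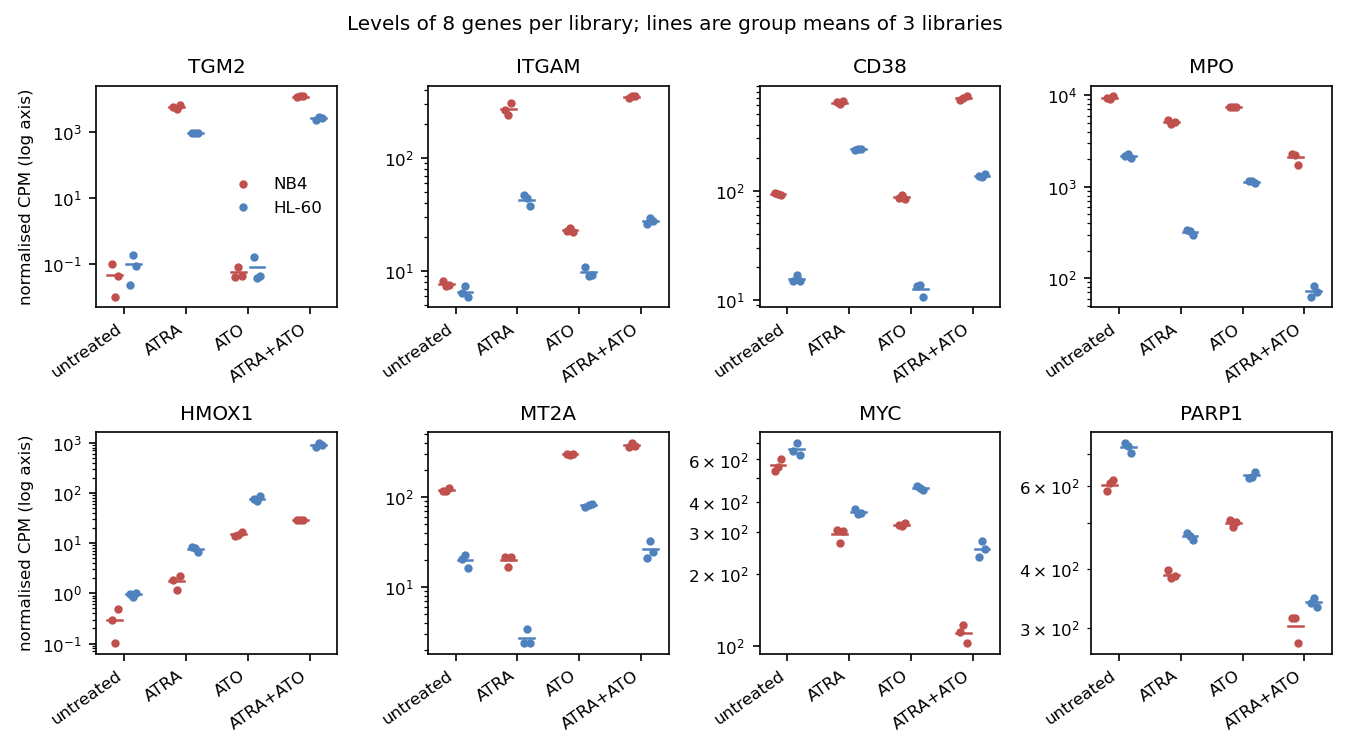
Levels of TGM2, ITGAM, CD38, MPO, HMOX1, MT2A, MYC and PARP1 in each library as normalised CPM on a log axis, with lines at the means of 3 libraries. Libraries with 0 reads are drawn at 0.01 CPM.

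HL-60 cells, which lack the PML-RARA fusion, were asked the same 6 questions. With ATRA, TGM2 rose from 0.0997±0.0823 to 927±21.5 CPM (13.06±0.141, adjusted p = 4.25e-25), the repressor gene HIC1 2910-fold (838 to 25000) and the lipid droplet gene PNPLA3 744-fold (147 to 32400). CD38 went from 15.6±1.12 to 239.7±3.14 CPM and ITGAM from 6.55±0.731 to 43±4.66 CPM (3.94±0.0738 and 2.71±0.103). CYTL1 fell at least 370-fold and CHAT 166-fold (77.5 to 400), and CSPG4 (-6.20±0.228), HDC (-5.75±0.265), RHEX (-5.6±0.157) and CA2 (-5.53±0.146) fell.

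Panel genes that also rose with ATRA in HL-60 were HMOX1 (3.01±0.148), CEBPE (2.27±0.0834) and PML (0.33±0.0817). RARA and ATM passed at 0.23 and 0.22, and lost the call without HL-60 untreated replicate 3 (0.15, adjusted p = 0.11) and without HL-60 untreated replicate 2 (0.11, adjusted p = 0.201). Falls were called for MPO (-2.76±0.0702), MT2A (-2.85±0.161), MYC (-0.87±0.0516), ELANE (-0.38±0.0894) and GCLM (-0.48±0.0679) and for PARP1 (-0.63±0.0375) and CHEK1 (-0.45±0.0511). BRCA1 and the cell-cycle inhibitor gene CDKN1A did not pass, at -0.15±0.0736 (adjusted p = 0.108) and -0.28±0.252 (adjusted p = 0.391).

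By list, for mature myeloid surface receptors, 25 of 32 measured members rose, 3 fell and 4 did not pass (26 rose and 3 fell adjusted over the list alone), a median log2 change of 1.9 (1.82 at the floor), with CR1 (3.42±0.0612), TREM1 (2.72±0.0631) and ITGAX (3.66±0.0976). By camera mature myeloid surface receptors moved higher (adjusted p = 1.01e-08, kept at adjusted p = 0.0272 with an estimated correlation). In DNA replication, 1 of 35 measured members rose, 30 fell and 4 did not pass (the same adjusted over the list alone), a median log2 change of -0.39, with MCM4 (-0.53±0.0399), MCM6 (-0.53±0.0396) and GINS2 (-0.96±0.0746). By camera DNA replication moved lower (adjusted p = 1.26e-09, kept at adjusted p = 0.0272 with an estimated correlation). For mismatch repair, 11 of 15 measured members fell and 4 did not pass (the same adjusted over the list alone), a median log2 change of -0.36. By camera mismatch repair moved lower (adjusted p = 4.51e-05, kept at adjusted p = 0.042 with an estimated correlation). For primary granule proteins, 4 of 15 measured members rose and 11 fell (the same adjusted over the list alone), a median log2 change of -0.79, with MS4A3 (-3.43±0.105) down and BPI (4.45±0.173) up. By camera primary granule proteins moved lower (adjusted p = 0.019, and adjusted p = 0.351 with an estimated correlation). In edgeR, 7723 of 15895 genes passed (4013 higher and 3710 lower), 2169 of them by at least 2-fold and 7655 with the same sign in all 3 batches. Camera called 14 of 47 lists higher and 11 lower, and 12 of these calls held with an estimated correlation. Between 6955 and 7223 genes were called without 1 library.

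With ATO alone, HL-60 cells raised HMOX1 from 0.955±0.0837 to 76.6±8.03 CPM (6.33±0.12, adjusted p = 6.07e-20). The ferritin gene FTH1, the quinone reductase gene NQO1 and VWA5A (2.85±0.0713), ACP5 (2.28±0.166) and FGR (2.25±0.0758) rose as well (2.52±0.0528 for FTH1 and 2.22±0.0596 for NQO1). The antigen presentation gene HLA-B fell from 162±7.71 to 25.1±2.97 CPM (-2.69±0.0656), with CYTL1 (-4.9±0.203), CHAT (-3.68±0.206) and TERT (-1.94±0.186). In the panel, MT2A (2.03±0.128), GCLM (1.26±0.0659), CEBPE (0.59±0.0853) and ITGAM (0.58±0.108) rose and MPO (-0.94±0.0661), MYC (-0.53±0.0513), CD38 (-0.32±0.0769) and PARP1 (-0.2±0.0373) fell, while CHEK1 (-0.05±0.0507, adjusted p = 0.493) and BRCA1 (-0.05±0.0736, adjusted p = 0.645) did not pass.

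For NRF2 target genes, 23 of 28 measured members rose and 5 did not pass (25 rose and 1 fell adjusted over the list alone), a median log2 change of 0.69, with ME1 (1.79±0.0677). Camera called NRF2 target genes higher (adjusted p = 1.28e-16, kept at adjusted p = 0.037 with an estimated correlation). For metallothioneins, 6 of 6 measured members rose (the same adjusted over the list alone), a median log2 change of 1.41. Camera called metallothioneins higher (adjusted p = 6.03e-05, kept at adjusted p = 0.0288 with an estimated correlation). For ribosome biogenesis, 29 of 32 measured members fell and 3 did not pass (30 fell adjusted over the list alone), a median log2 change of -0.29. Camera called ribosome biogenesis lower (adjusted p = 6.28e-16, kept at adjusted p = 0.0119 with an estimated correlation). For interferon-stimulated genes, 17 of 32 measured members rose, 1 fell and 14 did not pass (17 rose and 2 fell adjusted over the list alone), a median log2 change of 0.35. Camera called interferon-stimulated genes higher (adjusted p = 0.000313, kept at adjusted p = 0.0288 with an estimated correlation). For mitochondrially encoded mRNAs, 12 of 13 measured members fell and 1 did not pass (13 fell adjusted over the list alone), a median log2 change of -0.52, and their share of counts was 5.98±0.308% in untreated and 4.68±0.192% in ATO libraries. Camera called mitochondrially encoded mRNAs lower (adjusted p = 9.02e-09, and adjusted p = 0.176 with an estimated correlation). For ATF4 target genes, which answer amino acid and haem stress, 20 of 26 measured members rose and 6 did not pass (22 rose adjusted over the list alone), a median log2 change of 0.33, with NUPR1 (1.35±0.0558), DDIT4 (1.14±0.0863) and PSAT1 (0.44±0.0455). Camera called ATF4 target genes higher (adjusted p = 1.68e-08, and adjusted p = 0.111 with an estimated correlation). In edgeR, 4554 of 15895 genes passed (2625 higher and 1929 lower), 678 of them by at least 2-fold and 4504 with the same sign in all 3 batches. Camera called 17 of 47 lists higher and 10 lower, and 4 of these calls held with an estimated correlation. Between 3586 and 4201 genes were called without 1 library.

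With the combination in HL-60, HMOX1 reached 912±93 CPM (9.90±0.119, adjusted p = 1.65e-24) and TGM2 2611±244 CPM (14.55±0.141). ANGPTL4 rose at least 201-fold, PTGES 5990-fold (1460 to 43600) and the stress gene DDIT4L at least 136-fold. CYTL1 fell at least 298-fold, the relaxin receptor gene RXFP1 at least 80.7-fold, LRRC14B 558-fold (245 to 2310) and CSPG4 289-fold (111 to 1580). MPO went from 2169±124 to 71.8±10.1 CPM (-4.91±0.0784). Further panel genes that rose were CD38 (3.13±0.0724), ITGAM (2.09±0.104), CEBPE (2.04±0.0837), GCLM (2.26±0.067), CDKN1A (1.18±0.24) and RARA (0.36±0.0745), while MT2A passed at 0.40 but not without replicate 2 of the combination (0.19, adjusted p = 0.118).

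The repair gene PARP1 fell after the HL-60 combination, from 725±17.8 to 340.1±7.81 CPM (-1.09±0.0379). CHEK1 (-0.62±0.0516), BRCA1 (-0.35±0.0741), MYC (-1.38±0.0523) and ELANE (-2.36±0.0971) fell as well, and ATM (0.16±0.0782, adjusted p = 0.0783) and PML (0.08±0.0828, adjusted p = 0.452) did not pass. Over the same 8 lists, 98 of 163 members fell (60.1%, all genes 29.7%) and 18 rose, a median of -0.31. With ATRA alone 82 fell (50.3%, all genes 23.3%) and 8 rose, and with ATO alone 31 (19%, 12.1%) and 10. The interaction median was -0.073. The 9-list class gave 103 falls and 32 rises of 188, a median of -0.27.

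By pathway in HL-60 given the combination, for homologous recombination, 3 of 30 measured members rose, 23 fell and 4 did not pass (the same adjusted over the list alone), a median log2 change of -0.45, with RAD54L (-1.45±0.0697), BLM (-0.97±0.0548) and EXO1 (-0.85±0.0536). Camera called the list lower (adjusted p = 0.000169, and adjusted p = 0.0562 with an estimated correlation). For the Fanconi anaemia pathway, 2 of 20 measured members rose, 14 fell and 4 did not pass (the same adjusted over the list alone), a median log2 change of -0.36, with FANCE (-1.64±0.0921) and FANCG (-1.06±0.0675). By camera the list moved lower (adjusted p = 0.0043, and adjusted p = 0.0562 with an estimated correlation). For base excision repair, 2 of 24 measured members rose, 17 fell and 5 did not pass (the same adjusted over the list alone), a median log2 change of -0.53, with MPG (-3.08±0.0915) and UNG (-1.46±0.0558). Camera called the list lower (adjusted p = 0.000316, and adjusted p = 0.0562 with an estimated correlation). For mismatch repair, 11 of 15 measured members fell and 4 did not pass (the same adjusted over the list alone), a median log2 change of -0.57, with LIG1 (-1.10±0.0536) and MSH6 (-0.85±0.0536). Camera called the list lower (adjusted p = 0.000159, and adjusted p = 0.061 with an estimated correlation). For damage checkpoint signalling, 2 of 26 measured members rose, 19 fell and 5 did not pass (the same adjusted over the list alone), a median log2 change of -0.32, with WEE1 (-0.80±0.0476) and H2AX (-1.19±0.0807). By camera the list moved lower (adjusted p = 0.00228, and adjusted p = 0.152 with an estimated correlation). For non-homologous end joining, 3 of 18 measured members rose, 8 fell and 7 did not pass (the same adjusted over the list alone), a median log2 change of -0.23, with LIG4 (1.25±0.0963) up. By camera the list did not pass (adjusted p = 0.116).

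Of NRF2 target genes, 22 of 28 measured members rose, 4 fell and 2 did not pass (the same adjusted over the list alone), a median log2 change of 1.54, with FTH1 (3.74±0.0556), PGD (2.75±0.0475) and NQO1 (2.94±0.0608). By camera NRF2 target genes moved higher (adjusted p = 1e-07, and adjusted p = 0.0906 with an estimated correlation). In DNA replication, 1 of 35 measured members rose and 34 fell (the same adjusted over the list alone), a median log2 change of -0.74. Camera called DNA replication lower (adjusted p = 5.13e-12, and adjusted p = 0.0562 with an estimated correlation). For primary granule proteins, 4 of 15 measured members rose and 11 fell (the same adjusted over the list alone), a median log2 change of -3.43, with PRTN3 (-4.73±0.0977). Camera called primary granule proteins lower (adjusted p = 0.00138, and adjusted p = 0.197 with an estimated correlation). In edgeR, 9598 of 15895 genes passed (4885 higher and 4713 lower), 3362 of them by at least 2-fold and 9461 with the same sign in all 3 batches. Camera called 12 of 47 lists higher and 11 lower, and none of these calls held with an estimated correlation. Replicate 2 of this group also stood apart, with a chi-square per degree of freedom of 29.1 and 20.6 in its pairs against 6.01 in the remaining pair. Between 9084 and 9614 genes were called without 1 library.

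**Figure D3:**
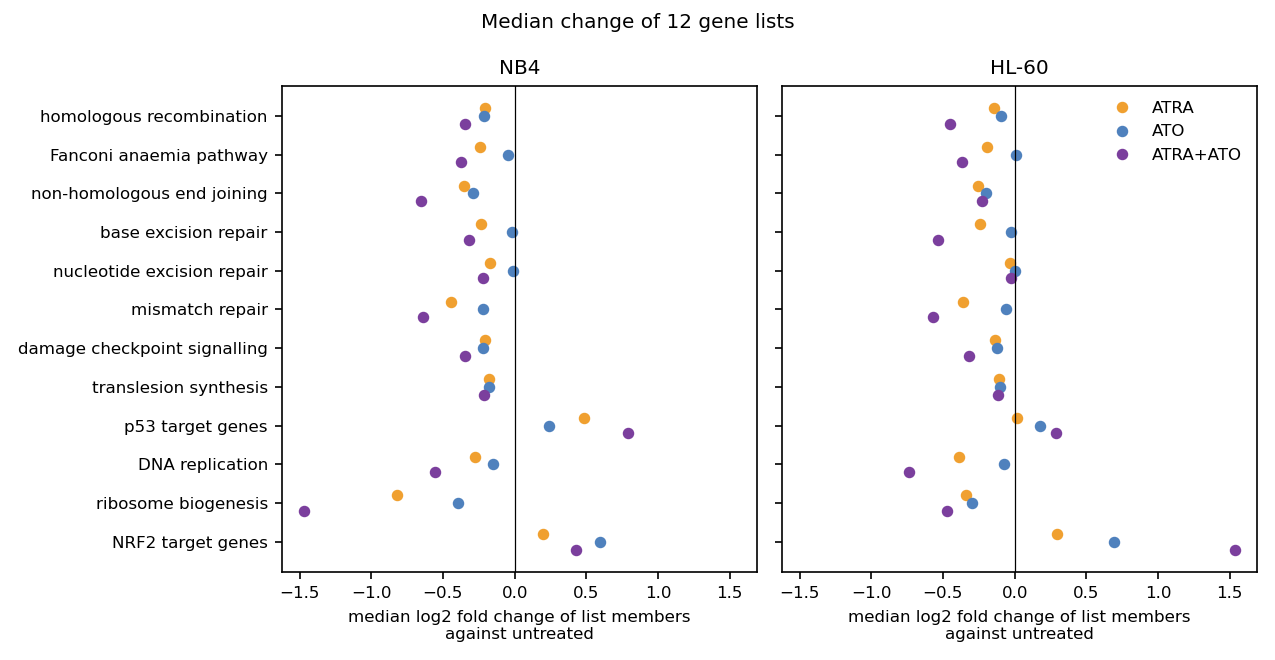
Median log2 change against untreated of 12 gene lists in NB4 and HL-60. With other scaling the median changed sign for the Fanconi anaemia pathway, base excision repair and nucleotide excision repair in NB4 with ATO, for p53 target genes in HL-60 with ATRA, and for the Fanconi anaemia pathway and nucleotide excision repair in HL-60 with ATO.

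What ATO added to ATRA in HL-60 was led by HMOX1, from 7.65±0.761 to 912±93 CPM (6.90±0.0943), and by MMP1 (4.22±0.353), RND3 (4.21±0.333) and CCL4 (4.21±0.228), a collagenase, a small GTPase and a chemokine. The granule protease gene PRTN3 fell (-3.95±0.0947), with TSPOAP1 (-3.94±0.0932), CCR2 (-3.79±0.0894) and PLD4 (-3.79±0.189). In the panel, MT2A (3.25±0.16), GCLM (2.74±0.0686), TGM2 (1.49±0.0648) and CDKN1A (1.46±0.244) rose and MPO (-2.16±0.0706), ELANE (-1.98±0.0964), CD38 (-0.81±0.0633) and PARP1 (-0.46±0.0376) fell.

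For NRF2 target genes in this comparison, 22 of 28 measured members rose and 6 did not pass (23 rose adjusted over the list alone), a median log2 change of 0.99. Camera called NRF2 target genes higher (adjusted p = 7.13e-14, and adjusted p = 0.0831 with an estimated correlation). For primary granule proteins, 13 of 15 measured members fell and 2 did not pass (14 fell adjusted over the list alone), a median log2 change of -1.98. By camera primary granule proteins moved lower (adjusted p = 8.14e-08, and adjusted p = 0.0831 with an estimated correlation). For DNA replication, 26 of 35 measured members fell and 9 did not pass (the same adjusted over the list alone), a median log2 change of -0.27. By camera DNA replication moved lower (adjusted p = 4.48e-09, and adjusted p = 0.0831 with an estimated correlation). In edgeR, 6982 of 15895 genes passed (3498 higher and 3484 lower), 1219 of them by at least 2-fold and 6818 with the same sign in all 3 batches. Camera called 7 of 47 lists higher and 10 lower, and none of these calls held with an estimated correlation. Between 6136 and 7422 genes were called without 1 library.

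What ATRA added to ATO in HL-60 included TGM2, up 32000-fold (15100 to 89600), PTGES 21600-fold (2000 to 441000) and CYP26B1 at least 126-fold. LRRC14B fell 344-fold (150 to 1410), CSPG4 185-fold (70.7 to 1010) and the rhomboid gene RHBDF1 93.3-fold (51.2 to 235). MPO (-3.97±0.0753), ELANE (-2.5±0.0973), MT2A (-1.63±0.127) and PARP1 (-0.89±0.0377) fell and HMOX1 (3.58±0.0769), CD38 (3.45±0.0738) and ITGAM (1.51±0.0993) rose.

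In DNA replication, 2 of 35 measured members rose and 33 fell (the same adjusted over the list alone), a median log2 change of -0.66. Camera called DNA replication lower (adjusted p = 8.6e-12, and adjusted p = 0.0596 with an estimated correlation). For primary granule proteins, 3 of 15 measured members rose and 12 fell (the same adjusted over the list alone), a median log2 change of -3.06. Camera called primary granule proteins lower (adjusted p = 0.000239, and adjusted p = 0.197 with an estimated correlation). For mitochondrially encoded mRNAs, 12 of 13 measured members rose and 1 fell (the same adjusted over the list alone), a median log2 change of 0.48. By camera mitochondrially encoded mRNAs moved higher (adjusted p = 0.00185, and adjusted p = 0.388 with an estimated correlation). In edgeR, 8656 of 15895 genes passed (4367 higher and 4289 lower), 2534 of them by at least 2-fold and 8496 with the same sign in all 3 batches. Camera called 10 of 47 lists higher and 10 lower, and none of these calls held with an estimated correlation. With library sizes alone all log2 changes moved by a median of -0.101 and the share of called genes that were higher went from 50.5% to 39.6%. Between 7911 and 8911 genes were called without 1 library.

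In the HL-60 interaction, the glutathione synthesis gene GCLM lay above the sum of the separate changes (1.48±0.0929), with TXNRD1 (0.92±0.0624) and MT2A (1.23±0.206). ELANE and PRTN3, which encode neutrophil proteases, lay below it (-2.12±0.131 and -2.74±0.121), with MPO (-1.21±0.095), ITGAM (-1.20±0.142), CEBPE (-0.83±0.114), LYZ (-0.84±0.0612) and AZU1 (-1.90±0.148). RND3, at 0.0304±0.0264 CPM in untreated cells, 0.38±0.181 with ATRA, 0.0123±0.0213 with ATO and 7.15±0.641 with the combination, was above the sum, but not without untreated replicate 1 (4.73, adjusted p = 0.0736) or untreated replicate 3 (4.77, adjusted p = 0.0715).

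For primary granule proteins, 13 of 15 measured members lay below the sum and 2 did not pass (the same adjusted over the list alone), a median log2 change of -1.49. By camera primary granule proteins moved lower (adjusted p = 1.73e-07, and adjusted p = 0.127 with an estimated correlation). For NRF2 target genes, 14 of 28 measured members lay above the sum, 3 lay below the sum and 11 did not pass (the same adjusted over the list alone), a median log2 change of 0.42. By camera NRF2 target genes moved higher (adjusted p = 9.4e-05, and adjusted p = 0.189 with an estimated correlation). For ribosome biogenesis, 16 of 32 measured members lay above the sum and 16 did not pass (17 lay above the sum adjusted over the list alone), a median log2 change of 0.21. By camera ribosome biogenesis moved higher (adjusted p = 2.07e-05, and adjusted p = 0.127 with an estimated correlation). In edgeR, 5170 of 15895 genes passed (2287 above the sum and 2883 below it), 947 of them by at least 2-fold and 4989 with the same sign in all 3 batches. Camera called 6 of 47 lists higher and 9 lower, and none of these calls held with an estimated correlation. Between 4502 and 6208 genes were called without 1 library.

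Whether the lines answered ATRA differently was tested on the difference of their log2 changes, NB4 minus HL-60, with all 24 libraries. ITGAM (2.43±0.134), CDKN1A (4.25±0.36) and MPO (1.86±0.109) were higher in the NB4 response. The channel gene KCNH4 went from 0.0577±0.0792 to 71.8±2.76 CPM in NB4 and from 1.66±0.184 to 4.33±0.492 CPM in HL-60. CD38 rose less in NB4 (-1.17±0.0875). PARP1 (-0.02±0.0649, adjusted p = 0.906), CHEK1 (-0.18±0.0948, adjusted p = 0.157) and BRCA1 (-0.12±0.136, adjusted p = 0.543) did not differ by the test.

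For interferon-stimulated genes, 29 of 37 measured members were higher, 1 was lower and 7 did not pass (the same adjusted over the list alone), a median log2 change of 1.58 (1.54 at the floor). By camera interferon-stimulated genes moved higher (adjusted p = 3.23e-11, kept at adjusted p = 0.00218 with an estimated correlation). For NADPH oxidase, 8 of 10 measured members were higher, 1 was lower and 1 did not pass (the same adjusted over the list alone), a median log2 change of 1.05. Camera called NADPH oxidase higher (adjusted p = 1.66e-06, kept at adjusted p = 0.0177 with an estimated correlation). For MHC class I presentation, 14 of 17 measured members were higher and 3 did not pass (the same adjusted over the list alone), a median log2 change of 1.17. By camera MHC class I presentation moved higher (adjusted p = 3.29e-08, kept at adjusted p = 0.0177 with an estimated correlation). In edgeR, 6185 of 17930 genes passed (3178 higher in the NB4 response and 3007 lower), 2138 of them by at least 2-fold and 6093 with the same sign in all 3 batches. Camera called 12 of 47 lists higher and 3 lower, and 7 of these calls held with an estimated correlation. Between 5666 and 6442 genes were called without 1 library. TGM2 passed at 3.73 but not without HL-60 untreated replicate 2 (2.90, adjusted p = 0.0584) or in limma-voom (3.72, adjusted p = 0.149).

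The same test of the difference was made for ATO. The hydroxylase gene CYP1B1 went from 28±0.763 to 2.73±0.314 CPM in NB4 and from 33.3±1.53 to 40.3±1.52 CPM in HL-60 (-3.60±0.153). ITGAM (1.03±0.141), MPO (0.64±0.108) and PML (0.47±0.105) were higher in the NB4 response, and MT2A (-0.68±0.157) and GCLM (-0.64±0.1) were lower. HMOX1 (-0.67±0.4, adjusted p = 0.316) and PARP1 (-0.04±0.0648, adjusted p = 0.753) did not differ by the test.

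For NADPH oxidase, 8 of 10 measured members were higher, 1 was lower and 1 did not pass (the same adjusted over the list alone), a median log2 change of 0.56. By camera NADPH oxidase moved higher (adjusted p = 3.23e-09, kept at adjusted p = 0.00537 with an estimated correlation). For MHC class I presentation, 11 of 17 measured members were higher and 6 did not pass (14 were higher adjusted over the list alone), a median log2 change of 0.56. Camera called MHC class I presentation higher (adjusted p = 2.22e-11, kept at adjusted p = 0.00537 with an estimated correlation). In edgeR, 2349 of 17930 genes passed (1274 higher in the NB4 response and 1075 lower), 570 of them by at least 2-fold and 2319 with the same sign in all 3 batches. Camera called 4 of 47 lists higher and 5 lower, and 2 of these calls held with an estimated correlation. The share of called genes that were higher went from 54.2% to 70.4% with library sizes alone and to 44.2% with every gene of at least 1 read, so this share depends on the setting. Between 1857 and 2253 genes were called without 1 library.

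For the combination, ITGAM, MPO and CDKN1A were higher in the NB4 response (3.44±0.136, 2.77±0.111 and 2.85±0.348). The antigen presentation gene CD74 went from 0.0645±0.031 to 18.5±0.635 CPM in NB4 and from 503.5±22.4 to 116±12.7 CPM in HL-60. HMOX1 (-3.31±0.46), GCLM (-2.13±0.101), ATP1B1 (-6.05±0.192) and MYC (-0.92±0.0878) were lower in the NB4 response. PARP1 (0.12±0.065, adjusted p = 0.121), CHEK1 (-0.22±0.0952, adjusted p = 0.057) and BRCA1 (0.19±0.136, adjusted p = 0.272) did not pass. The 8-list repair genes had a median of -0.009, with 35.6% higher and 36.8% lower, against 24.9% and 22.7% of all genes.

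For ribosome biogenesis, 31 of 32 measured members were lower and 1 did not pass (the same adjusted over the list alone), a median log2 change of -1.08. Camera called ribosome biogenesis lower (adjusted p = 6.2e-16, kept at adjusted p = 0.0145 with an estimated correlation). For interferon-stimulated genes, 28 of 37 measured members were higher, 1 was lower and 8 did not pass (the same adjusted over the list alone), a median log2 change of 1.6 (1.56 at the floor). Camera called interferon-stimulated genes higher (adjusted p = 8.73e-08, kept at adjusted p = 0.0109 with an estimated correlation). For NRF2 target genes, 6 of 28 measured members were higher, 15 were lower and 7 did not pass (the same adjusted over the list alone), a median log2 change of -0.72 (-0.84 at the floor). Camera called NRF2 target genes lower (adjusted p = 0.000292, and adjusted p = 0.21 with an estimated correlation). In edgeR, 8524 of 17930 genes passed (4462 higher in the NB4 response and 4062 lower), 3619 of them by at least 2-fold and 8316 with the same sign in all 3 batches. Camera called 7 of 47 lists higher and 7 lower, and 6 of these calls held with an estimated correlation. All log2 changes moved by a median of 0.136 with library sizes alone. Between 8081 and 8566 genes were called without 1 library.

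Before any drug, the lines already stood far apart. The RNA-binding gene IGF2BP2 was higher in NB4 by 151-fold (74.9 to 447) and the lymphoid factor gene IKZF3 by 43.4-fold (24.2 to 88), with CD38 (2.37±0.0664), CEBPE (2.35±0.0816), MT2A (2.38±0.118) and MPO (1.91±0.0786). The amyloid precursor gene APP was lower in NB4 by at least 5720-fold, DENND2D by at least 1920-fold and the ketone-body gene OXCT1 by at least 1620-fold. ELANE stood at 0.209±0.0825 CPM in NB4 and 163±15.8 CPM in HL-60, and HMOX1 (-1.85±0.335), RARA (-0.91±0.0878), PARP1 (-0.47±0.0459) and ATM (-0.53±0.0925) were lower in NB4, while ITGAM (0.02±0.107, adjusted p = 0.879) and CHEK1 (0.14±0.0666, adjusted p = 0.0662) did not differ by the test. For MHC class I presentation, 2 of 17 measured members were higher, 14 were lower and 1 did not pass (2 were higher and 15 were lower adjusted over the list alone), a median log2 change of -0.60. By camera MHC class I presentation moved lower (adjusted p = 0.00767, and adjusted p = 0.299 with an estimated correlation). In edgeR, 11324 of 17930 genes passed (5220 higher in NB4 and 6104 lower), 5416 of them by at least 2-fold and 11112 with the same sign in all 3 batches. Camera called 3 of 47 lists higher and 7 lower, and none of these calls held with an estimated correlation. With library sizes alone all log2 changes moved by a median of 0.15 and the share of called genes higher in NB4 went from 46.1% to 55.4%, so the majority depends on the scaling. Between 10770 and 10865 genes were called without 1 library.

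How alike the responses were was measured by 5 correlations of log2 changes across genes, which are not independent replicates. Between the lines the correlation was 0.695 for ATRA, 0.495 for ATO and 0.659 for the combination over 14562 genes. Within single batches it was 0.621, 0.622 and 0.626 for ATRA, 0.373, 0.361 and 0.375 for ATO, and 0.574, 0.612 and 0.609 for the combination. Of genes called in both lines, 2570 rose with ATRA in both against 1170 expected from the separate counts, 2498 fell in both against 1104, and 601 moved in opposite directions. For ATO these were 1464 against 534.8, 1310 against 407, and 163, and for the combination 2817 against 1581, 2886 against 1591, and 1451.

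Within a line, the ATRA and ATO responses correlated at 0.598 in NB4 (0.561, 0.576 and 0.54 within batches) and 0.552 in HL-60 (0.497, 0.502 and 0.525). They share their untreated libraries, and 20 simulations in which neither drug changed any gene gave 0.503 and 0.507 from that sharing alone. Many genes changed in the data, so these values do not show what the sharing adds to the observed correlations. With the same limit, the covariance was 0.946 in NB4 against 0.0398 simulated and 0.442 in HL-60 against 0.0396. Its size depends on the setting: 0.4729 and 0.1389 at a mean CPM of at least 10, and 0.5469 and 0.2608 with a prior count of 2. The simulations were not repeated in these settings. In NB4, 2576 genes rose with each drug against 1083 expected, 2366 fell with each against 918.9, and 422 moved in opposite directions. In HL-60 these were 1810 against 662.7, 1261 against 450.2, and 365. Expected numbers assume independence, which shared untreated libraries break. Simulations of no change (0 called with both) cannot size the effect.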

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

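The tests of RNA quality, of a single library, of matched lists for the 9-list class and the shuffles within each line were chosen only after the results were seen. The section opens with values in which the lines differed in their response to the same drug. Log2 values are NB4 minus HL-60, list values are medians, and the number in parentheses after a list is its adjusted p with an estimated correlation.

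For ATRA, 6185 genes differed between the lines. Lists called by camera were ribosome biogenesis -0.53 (0.0311), primary granule proteins 0.91 (0.292), mature myeloid surface receptors 1.54 (0.029), NADPH oxidase 1.05 (0.0177), retinoid response genes 2.13 (0.0657), interferon-stimulated genes 1.58 (0.00218), MHC class I presentation 1.17 (0.0177), heat shock genes -0.52 (0.0475), unfolded protein response -0.34 (0.0721), death receptors and caspases 0.48 (0.00962), chemokines and inflammatory cytokines 2.05 (0.0578), NF-kB feedback genes 1.11 (0.0723), coagulation and fibrinolysis 0.85 (0.221), cholesterol synthesis 0.64 (0.221) and glycolysis and hypoxia genes 0.89 (0.225). Panel genes were CYP26A1 4.10, RARA 0.45, PML 0.71, ITGAM 2.43, CD38 -1.17, TGM2 3.73, MPO 1.86, ELANE -5.75 and CDKN1A 4.25. CYP26A1 in HL-60 rests on few reads. ELANE went from 0.209±0.0825 CPM to 0 reads in NB4, so the prior count sets the size of its difference. Without HL-60 untreated replicate 1 the CYP26A1 difference was 0.52 (adjusted p = 0.805), and it lost its call in limma-voom (adjusted p = 0.08), as did ELANE (adjusted p = 0.0509).

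For ATO, 2349 genes differed. Lists called by camera were ribosome biogenesis -0.0649 (0.65), mature myeloid surface receptors 0.75 (0.221), NADPH oxidase 0.56 (0.00537), MHC class I presentation 0.56 (0.00537), NRF2 target genes -0.19 (0.633), ATF4 target genes -0.18 (0.328), unfolded protein response -0.15 (0.0682), death receptors and caspases 0.19 (0.0667) and cholesterol synthesis -0.15 (0.65). Panel genes were PML 0.47, ITGAM 1.03, CEBPE 0.44, MYC -0.26, MPO 0.64, GCLM -0.64 and MT2A -0.68. MYC lost its call with library sizes alone (adjusted p = 0.118), with the replicate block (adjusted p = 0.0531) and without any of 10 single libraries.

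For the combination, 8524 genes differed. Lists called by camera were ribosome biogenesis -1.08 (0.0145), primary granule proteins 1.6 (0.11), mature myeloid surface receptors 2.28 (0.0641), NADPH oxidase 1.79 (0.0281), retinoid response genes 2.83 (0.0936), interferon-stimulated genes 1.6 (0.0109), MHC class I presentation 1.35 (0.0281), NRF2 target genes -0.72 (0.21), heat shock genes -0.95 (0.0281), ATF4 target genes -0.31 (0.446), unfolded protein response -0.86 (0.0109), death receptors and caspases 0.56 (0.0641), oxidative phosphorylation -0.21 (0.561) and mitochondrially encoded mRNAs -0.64 (0.561). Panel genes were CYP26A1 5.13, RARA 0.64, PML 1.07, ITGAM 3.44, CEBPE 0.43, TGM2 3.31, MYC -0.92, MPO 2.77, HMOX1 -3.31, GCLM -2.13, MT2A 1.28, CDKN1A 2.85 and ATM 0.49. TGM2 lost its call without HL-60 untreated replicate 2 for ATRA (adjusted p = 0.0584) and for the combination (adjusted p = 0.083), and in limma-voom for both (adjusted p = 0.149 and 0.171). CYP26A1 fell to 1.52 for the combination without HL-60 untreated replicate 1 (adjusted p = 0.85).

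Mitochondrially encoded mRNAs were lower with ATO in both lines by camera, with adjusted p = 0.466 in NB4 and adjusted p = 0.176 in HL-60 with an estimated correlation. With library sizes alone the median in the line nearer 0 was -0.498, so scaling does not account for it. Cytosolic ribosomal protein mRNAs moved by at most 0.112, which argues against a difference in RNA quality, but they are not members of the pattern and RNA integrity was not analysed here, so it stays open.

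Repair and checkpoint genes, 8 lists grouped after the data were seen, had lower medians with the combination in both lines. No repair list kept its call with an estimated correlation (homologous recombination, adjusted p = 0.38 in NB4 and 0.0562 in HL-60). With library sizes alone the median nearer 0 was -0.292, so scaling does not account for it. Of random lists matched on expression and exon length 0% lay as low, for the grouping and the 9-list class fixed beforehand. In NB4 the margin was small (-0.372 against -0.367 for the lowest, -0.327 against -0.326 for the class). Expression and length stay open there (such lists centred on -0.0966), but not in HL-60 (-0.31 against -0.173). Only 1 member was in the replication and mitosis lists (median -0.302 without it), so a link to slower division stays open.

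NRF2 target genes were called lower in the NB4 response to the combination by camera, with adjusted p = 0.21 with an estimated correlation. Of 28 members, 15 were lower, 6 were higher and 7 did not pass. The median difference was -0.584 with library sizes alone, so scaling does not account for it. With each library left out in turn it ran from -0.823 to -0.689, so a single library does not account for it either. This test replaced an earlier one on HMOX1 alone (27.8 times), with bounds set after its values were seen.

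Splits of the same libraries asked whether other groupings gave as many called genes. For the 11 comparisons of a pair of groups the number of splits, 10, was too few to judge, and in each only 1 split, the real grouping, reached the real value. The real values and the highest other split were 9806 and 0 for ATRA, 6674 and 0 for ATO and 11164 and 0 for the combination in NB4, with 6219 and 0 against ATRA and 9312 and 0 against ATO. In HL-60 they were 7723 and 0, 4554 and 0, 9598 and 0, 6982 and 0, and 8656 and 0 in the same order, and 11324 and 1 for the untreated lines.

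Regroupings over 4 groups still carry the real effects of drug and line, so they do not measure chance. For the interactions, 1 of 40 splits, the real grouping, reached 3056 in NB4 (highest other 958) and 5170 in HL-60 (highest other 8). For the differences between lines, 2 of 33 splits reached the real value for ATRA (6185, highest other 7648) and 4 of 33 for ATO (2349, highest other 8033). For the combination 1 of 33 did (8524, highest other 6340). Shuffles within each line gave 3 of 33 for ATRA (highest other 7387), 4 of 33 for ATO (highest other 4161) and 1 of 33 for the combination (highest other 8294).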

How the results depend on the processing

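Halved counts and the correlations with 1 library left out were added after the results were seen. At an adjusted p below 0.01 the called genes were 1824 for the NB4 interaction, 3020 for HL-60 with ATO and 1344 for the difference between lines in the response to ATO, against 3056, 4554 and 2349. Over all comparisons camera called 306 lists, 32 with an estimated correlation and 576 by fry, which reversed 4 list results. The correlation between lines for ATRA was 0.7725 among genes with a mean CPM of at least 10, 0.6986 with a prior count of 2, and 0.6735 to 0.6813 without 1 library. For ATO it was 0.6673, 0.5371, and 0.4481 to 0.4733, and for the combination 0.6209 to 0.6524, lowest without HL-60 ATRA+ATO replicate 2. Between ATRA and ATO it was 0.7243 at a mean CPM of at least 10 and 0.5415 to 0.6294 without 1 library in NB4. In HL-60 it was 0.5672, 0.5232 with a prior count of 2, and 0.4984 to 0.60. Called genes also went from mostly higher to mostly lower with library sizes alone, for ATRA in NB4 (52.2% to 47.5% higher) and HL-60 (52.0% to 46.2%) among others. No call of a named gene was reversed in any setting. The cause was not tested for any of these moved results.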

Other observations

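Lists not described so far included markers of other blood cells and metabolism. In NB4 with the combination, for erythroid markers 3 of 4 measured members rose and 1 fell (the same adjusted over the list alone), a median log2 change of 0.66. Camera did not call erythroid markers (adjusted p = 0.54). For megakaryocyte markers 5 of 5 measured members rose (the same adjusted over the list alone), a median log2 change of 4.32. Camera called megakaryocyte markers higher (adjusted p = 0.00379, and adjusted p = 0.0982 with an estimated correlation). For cholesterol synthesis 15 of 22 measured members rose and 7 did not pass (the same adjusted over the list alone), a median log2 change of 0.33. Camera called cholesterol synthesis higher (adjusted p = 0.0278, and adjusted p = 0.493 with an estimated correlation). For glycolysis and hypoxia genes 16 of 28 measured members rose, 5 fell and 7 did not pass (the same adjusted over the list alone), a median log2 change of 0.61. Camera called glycolysis and hypoxia genes higher (adjusted p = 0.0451, and adjusted p = 0.672 with an estimated correlation).

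In HL-60 with the combination, for cholesterol synthesis 15 of 23 measured members rose, 3 fell and 5 did not pass (17 rose and 3 fell adjusted over the list alone), a median log2 change of 0.32. By camera cholesterol synthesis moved higher (adjusted p = 0.00101, and adjusted p = 0.0951 with an estimated correlation). For eosinophil, basophil and mast cell markers 3 of 12 measured members rose, 8 fell and 1 did not pass (the same adjusted over the list alone), a median log2 change of -1.61. Camera did not call eosinophil, basophil and mast cell markers (adjusted p = 0.227). The mitochondrial share of counts was 5.71±0.422% in HL-60 and 3.44±0.384% in NB4 with the combination.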
